A study of Mus musculus with 4 samples.

How the data were processed

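The assay was individual-nucleotide crosslinking and immunoprecipitation (iCLIP) of ZFP36L1, an RNA-binding protein of the ZFP36 family, which binds AU-rich elements in mRNA and promotes mRNA decay. In iCLIP, ultraviolet light joins a protein to the RNA it touches, the complexes are immunoprecipitated, and reverse transcription stops beside the crosslinked base, so that the end of each cDNA marks a contact to the nucleotide. Per the labels' protocols, B cells came from lymph nodes of C57BL/6 mice after removal of cells carrying Ter119, CD11b, CD43 or CD5. They were stimulated for 48 hours with lipopolysaccharide at 10 µg/ml, interleukin 4 at 10 ng/ml and interleukin 5 at 5 ng/ml. Living cells were then exposed to 300 mJ/cm2 of ultraviolet light, and complexes were recovered with an antibody that the labels call Brf1/2, older names of ZFP36L1 and ZFP36L2. Complexes of the right size were excised from a membrane. The 4 libraries were made in independent experiments and sequenced as 100 bp single reads. The reverse transcription primers carried a barcode of 3 known and 4 random bases, and 4 random bases give 256 different codes. Whether these codes were used to collapse PCR copies is not given in the sources used here. All 4 libraries were wild type and formed 1 group, so every comparison was made within it, between RNA regions, genes, gene lists and sequences. No control immunoprecipitation and no RNA abundance measurement were analysed here.

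The authors deposited 1 table in which the 4 libraries are pooled, with no column per library. The submitters' processing notes name the mouse genome build mm10 and Bowtie, with no version. The peak caller, the counting of reads or cDNAs and the way the libraries were combined are not given in the sources used here. Per the file headers, each crosslinked position has a chromosome, a strand, a segment type, a gene name and 4 values. The first deposited value is a signed score whose size is a whole-number count and whose sign equalled the strand at 100% of positions. The header calls these counts unknown, so it stays open whether a count is a read or a collapsed cDNA. The second deposited score is the signed sum of counts within 15 nt on each side in the same gene and segment. A recomputed sum was equal at 100% of positions. The third deposited value, headed as a p-value, is a fraction: the share of positions of the same gene segment whose 15 nt sum is at least as large. A recomputed rank share was equal within 0.0001 at 100% of the positions in gene segments, so this column was used as a rank and not as a test. The fourth deposited score is a false discovery rate (FDR) that reaches 4.61 and exceeds 1 at 4297 positions, which is why it was used only as the authors' own ranking, with thresholds of 0.05 and 0.01. How it was computed is not given in the sources used here.

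The table holds 465794 positions with 572260 counts. A count of 1 was found at 93.1% of positions, so the median of single-position counts was 1 in each region and could not rank them. The 15 nt sum was used as peak height instead. The stricter setting planned as the better scoring part of the positions fell within a tie, because 62.1% of positions had a 15 nt sum of 1. It became a 15 nt sum of at least 2, which 37.9% of positions had. Positions in the table start at 0 and are written here counted from 1. The regions are the table's own segment types (3′UTR, coding sequence, 5′UTR, intron, non-coding RNA, intergenic and stretches at chromosome ends). Of 15075 gene entries, 14820 were matched to the GENCODE M21 annotation, which is on the same build as mm10, 14082 of them by symbol, 651 by synonym and 87 by identifier. Of the positions that the table places in a 3′UTR, 97.2% lay in a 3′UTR of the same gene in M21. The coding label was looser: 53.5% of these positions lay in M21 coding sequence, 24.7% in another exon and 19.1% in an M21 3′UTR. A gene with a 3′UTR missing from the authors' annotation can therefore appear without a 3′UTR position, and M21 regions were run as alternatives, with coding sequence first as planned and with the 3′UTR first as a choice made after the data were examined.

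Shares of positions have exact 95% binomial (Clopper-Pearson) intervals and summed counts have exact Poisson intervals. These intervals cover counting error only, since PCR copies are not independent molecules, and neighbouring positions of 1 transcript are not independent either. With the libraries pooled there is no spread between replicates, and no value here has an SD. A count of 0 allows up to 3 counts, or 0.000524% of the total. Densities are counts by the authors' labels per kb of M21 region over 12427 protein-coding genes with any position and an annotated 3′UTR. Peak heights in 3′UTRs were compared with those in introns and coding sequence by two-sided permutation tests of the median (100000 permutations). UAUUUA was searched within 25 nt of 36951 positions in 5191 3′UTRs and compared with 1000 draws of random positions in the same 3′UTRs, two-sided. Bootstrap intervals of odds ratios resampled genes. All pentamers and the 15 hexamers made of 4 U and 2 A were ranked in the same windows.

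Before the data were examined, 20 gene lists were fixed from textbook knowledge of activated B cells and of AU-rich mRNAs: G1/S, G2/M, cell cycle inhibitor, AU-rich cytokine and immediate early, ZFP36 family and AU-rich element binding protein, mRNA decay, B cell identity, plasma cell, V(D)J recombination and class switch, apoptosis, PI3K, mTOR and NF-kB, Notch, ribosomal protein, housekeeping, histone, non-coding RNA, and T cell, myeloid, erythroid and stromal markers. List members that the table names by an older symbol (Jchain, Adgre1 and Rn7s2) were matched by their M21 symbol, a step added after the data were examined, and members without any position were not tested. The share of a list's genes with a 3′UTR position was compared with that of the other genes by a two-sided Fisher's exact test, and with 10000 random lists matched on 3′UTR length in 10 classes. Summed 3′UTR counts (log2) of the list's genes with a position were compared with those of the other genes with one by two-sided permutation (100000 permutations). Both used the Benjamini-Hochberg adjustment over the lists tested, with a threshold of 0.05. The rule for named genes, also fixed then, took the 15 genes with the highest summed 3′UTR counts, up to 4 members of each list by 3′UTR counts, the 3 ZFP36 paralogs, the 5 leading genes of introns, coding sequence and non-coding RNA, and up to 3 members of each list without a 3′UTR position. It also took the highest position of the leading genes with its sequence. Mitochondrial, immunoglobulin, T cell receptor, rRNA and tRNA genes were left out of the 3′UTR ranking.

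The tests were checked on simulated data. Of 200 simulated lists of 20 genes, each built with the same high share of genes with a 3′UTR position, both tests called 100%. These were Fisher's test and the length-matched test. For Fisher's test this outcome was the same in each list by construction, so it does not measure power. Of 200 random lists, 6.0% passed with Fisher's test and 3.5% with the matched test. Of 200 random lists of genes with long 3′UTRs, 19.0% passed with Fisher's test and 2.0% with the matched test. A planted log2 shift of 2 in 10 genes was found in 98.5% of simulated lists, a shift of 1 in 41.0%, and no shift was called in 5.5%. In the motif test, a planted odds ratio of 7.00 was found as 6.96. Alternatives changed the threshold, the unit (counts, merged neighbours within 15 nt), the annotation, the motif, the window, the background and the weighting of genes. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.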

Results

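Contacts of ZFP36L1 with RNA were mapped by iCLIP in B cells from mouse lymph nodes that had been stimulated for 48 hours with lipopolysaccharide, interleukin 4 and interleukin 5. These stimuli drive resting B cells into the cell cycle and towards antibody secretion. The data came from 4 wild-type libraries of 4 independent experiments, pooled by the authors into 1 table of 465794 crosslinked positions with 572260 counts. The mitochondrial chromosome held 14860 counts (2.60%), and the 100 highest positions together held 2.42% of all counts. The authors' FDR was below 0.05 at 108052 positions, which held 205250 counts. Depth per library is not given in the sources used here, so no value below has a spread between replicates, and all intervals cover counting error only. The antibody's name covers ZFP36L2 as well, and contacts of ZFP36L2 were not separated from those of ZFP36L1 here.

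The first question was in which part of transcripts ZFP36L1 was crosslinked. Introns held the most positions, 64.9% of all (exact binomial 95% interval 64.7 to 65.0), followed by intergenic sequence with 19.7% (19.6 to 19.8). 3′UTRs, the mRNA part in which AU-rich elements lie, held 38009 positions, or 8.16% (8.08 to 8.24). Coding sequence held 22385 positions, or 4.81% (4.74 to 4.87), non-coding RNAs 2.06% (2.02 to 2.11) and 5′UTRs 0.284%. Relative to length the order was different. In 12427 protein-coding genes, 3′UTRs carried 1.83 counts per kb (Poisson 95% interval 1.82 to 1.85), coding sequence 0.878 (0.866 to 0.890), introns 0.383 (0.381 to 0.384) and 5′UTRs 0.310 (0.294 to 0.327). With the authors' labels over M21 lengths, the density in 3′UTRs was thus 4.79 times that in introns and 2.09 times that in coding sequence. With labels and lengths both from M21, an alternative chosen after the data were examined, it was 5.49 and 4.47 times. The order of introns and 5′UTRs turned round in that setting, with 0.371 (0.369 to 0.372) and 0.413 (0.395 to 0.432) counts per kb. The shares moved with the setting: intergenic sequence held 30.9% and introns 55.8% of the positions at an FDR below 0.01, and non-coding RNAs held 5.53% of counts. Of the positions labelled coding by the authors, 19.1% lay in an M21 3′UTR, and M21 regions gave 9.14% for 3′UTRs and 2.63% for coding sequence.

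**Figure D1:**
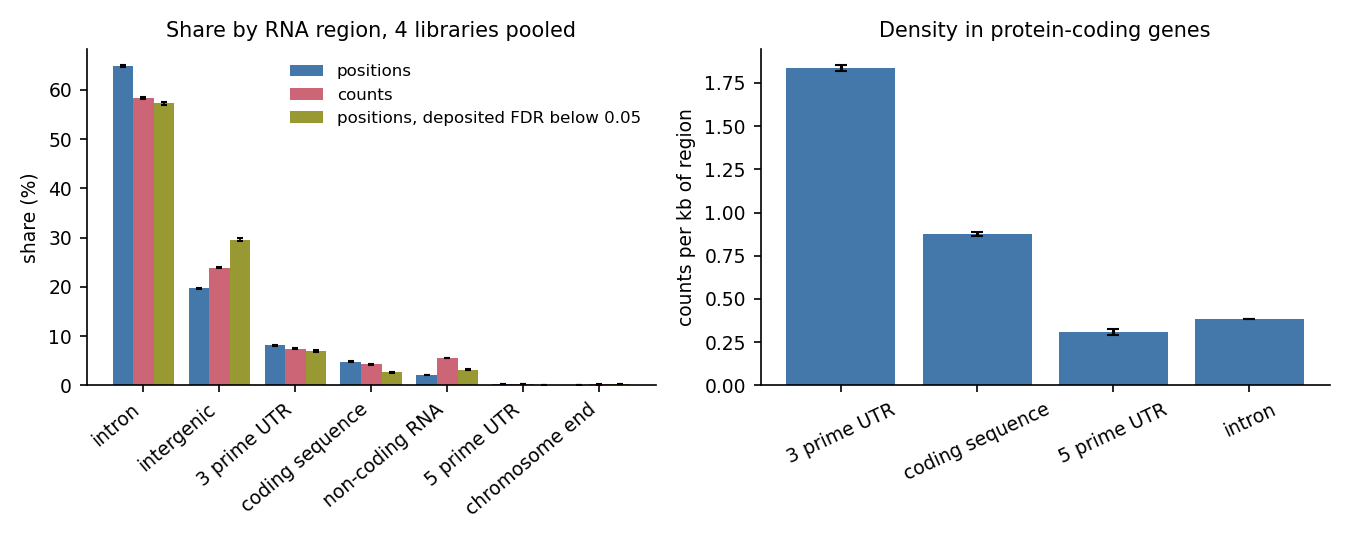
The left panel plots the share of positions, of counts and of positions at an FDR below 0.05 in each RNA region (percent, pooled over 4 libraries, exact binomial 95% intervals), and the right panel the counts per kb of region in 12427 protein-coding genes (Poisson 95% intervals). Introns hold 64.9% of positions, while 3′UTRs reach the highest density, 1.83 counts per kb.

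The second question was which mRNAs carried contacts in the 3′UTR. Of 12763 protein-coding genes with any position, 5351 (41.9%) had one in the 3′UTR, 11577 in an intron and 5340 in coding sequence, while 6948 had intron positions and none in the 3′UTR. The counts were unevenly spread. Exactly 1 count was found in 1551 of the genes with a 3′UTR position (29.0%), the median was 3 counts, and 114 genes with at least 50 counts held 25.5% of all 3′UTR counts. A position at an FDR below 0.05 was present in the 3′UTR of 949 genes, and at an FDR below 0.01 in 895.

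The highest 3′UTR count belonged to Zfp36l1, the mRNA of the immunoprecipitated protein itself, with 542 counts (Poisson 95% interval 497 to 590) and 180 positions at an FDR below 0.05. Nfkbia, which encodes the NF-kB inhibitor IkBa, followed with 515 counts (471 to 561) in a 3′UTR of 512 nt. Tnf, an inflammatory cytokine whose mRNA carries a classical AU-rich element, had 279 counts (247 to 314). The paralogs of Zfp36l1 were lower, with 92 counts for Zfp36 (74.2 to 113) and 73 for Zfp36l2 (57.2 to 91.8). Elavl1, which encodes the AU-rich element binding protein HuR, had 179 counts (154 to 207). Replication-dependent histone genes, whose mRNAs end in a stem-loop without a poly(A) tail, were also among the 15 leading genes: Hist1h4d with 322 counts (288 to 359), Hist1h3c with 273 (242 to 307) and Hist1h4a with 249 (219 to 282). Histone genes have near-identical copies, so the assignment of these counts to 1 copy is uncertain. The other leading genes were Ccdc50 with 311 counts, Flt3, a cytokine receptor, with 241, B2m, the light chain of MHC class I, with 196, and Actb, a cytoskeletal actin, with 161. Cdk5r1 followed with 144, Trim30a with 141, Dusp11 with 129 and Cd44, an adhesion receptor, with 126. In Flt3 only 1 count lay in the M21 3′UTR, so its region rests on the authors' annotation.

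The shape of these 3′UTR signals differed between genes. For Tnf and Zfp36l1 the 25 nt are counted from either end of a UAUUUA. The motif test further below is stricter and needs the whole UAUUUA within 25 nt of the position. In Tnf (chromosome 17, minus strand, 35199381 to 35200144, 3′UTR of 764 nt) 8 copies of UAUUUA lie between nt 420 and 635, and 209 of 279 counts (74.9%) fell within 25 nt of one, a zone that makes up 22.6% of the 3′UTR. In Zfp36l1 (chromosome 12, minus strand, 80107754 to 80109588, 3′UTR of 1672 nt) 5 copies lie between nt 968 and 1602, and 156 of the 533 counts that the authors and M21 both place in its 3′UTR, outside M21 coding sequence (29.3%), fell within 25 nt of one, a zone of 13.6% of its length. The highest 15 nt sums belonged to Hist1h4d, Nfkbia, Hist1h3c, Hist1h4a and Tnf. In Nfkbia the highest point was chromosome 12 position 55489460 (15 nt sum 276), in the 3′UTR sequence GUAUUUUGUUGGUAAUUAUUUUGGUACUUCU (55489445 to 55489475, minus strand). In Tnf it was chromosome 17 position 35199706 (15 nt sum 79), in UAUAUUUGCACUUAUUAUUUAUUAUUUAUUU (35199691 to 35199721, minus strand). The 3 histone genes had their highest points on chromosome 13 and these were Hist1h4d at 23581929 on the plus strand (15 nt sum 322), in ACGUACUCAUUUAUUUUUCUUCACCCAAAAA from 23581914 to 23581944, and Hist1h3c at 23745080 on the minus strand (273), in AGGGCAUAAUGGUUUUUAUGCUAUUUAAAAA from 23745065 to 23745095. In Hist1h4a the point was 23760834 on the minus strand (249), in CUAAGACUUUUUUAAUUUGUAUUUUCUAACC from 23760819 to 23760849.

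**Figure D2:**
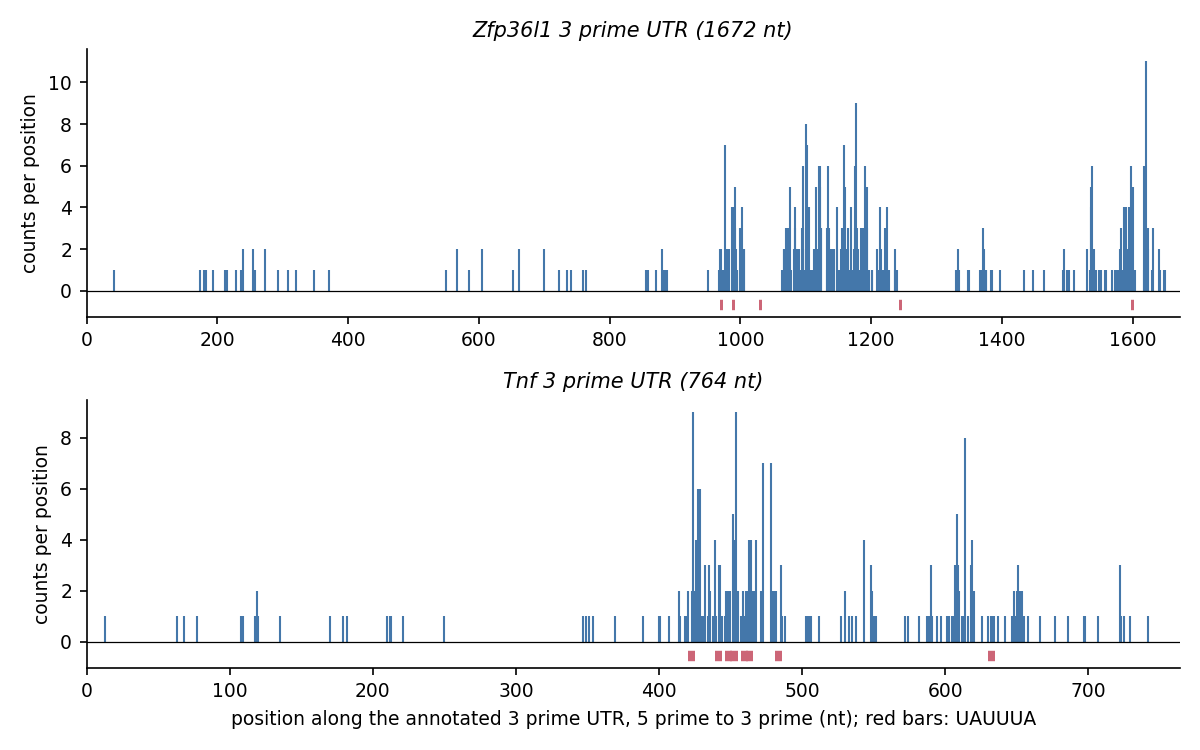
Counts per crosslinked position (vertical axis) are drawn along the annotated 3′UTRs of Zfp36l1 and Tnf (horizontal axis, nt from 5′ to 3′), with each UAUUUA as a red bar. In Tnf 74.9% of counts lie within 25 nt of a UAUUUA, in Zfp36l1 29.3%.

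The local height of contacts was compared between 3′UTRs, introns and coding sequence. The median 15 nt sum was 2 in 3′UTRs against 1 in introns and 1 in coding sequence (two-sided permutation p = 1e-05 for each, the smallest that 100000 permutations can give). The mean sums, a measure chosen after the data were examined, were 4.56 in 3′UTRs, 3.44 in introns and 3.37 in coding sequence, and in nuclear protein-coding genes alone the coding mean was 2.01. When each gene entered once per region with its median, the mean in 3′UTRs was 0.607 above that of coding sequence (permutation p = 1e-05). It was 0.114 above that of introns (permutation p = 0.477), so no difference from introns was found between these sets of genes. The 5358 genes with a 3′UTR median and the 12713 with an intron median were not the same set. They were not paired by gene, so a difference within genes was not tested. The median of the gene medians was 1 in each region and could not show a difference.

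The next question was whether contacts lay near the AU-rich sequence that ZFP36 proteins are known to bind. UAUUUA, the core of that element, was present within 25 nt of 18.0% of 36951 3′UTR positions, against 4.83% of random positions in the same 3′UTRs. This is an odds ratio of 4.34 (bootstrap 95% interval over genes 4.11 to 4.57, n = 36951 positions, two-sided p = 0.002, the smallest that 1000 draws can give). The longer element UUAUUUAUU had an odds ratio of 7.33, UAUUUAU 5.68 and the pentamer AUUUA 3.01. At positions with an FDR below 0.05 UAUUUA was near 37.7% against 5.53% of random positions (odds ratio 10.4), and at positions with a 15 nt sum of 1 near 8.92% (odds ratio 2.24). The motif was also enriched around coding positions, with 4.17% against 1.09% (odds ratio 3.94), and around 289147 intron positions, with 20.5% against 3.34% (odds ratio 7.48). With tandem UUUA repeats left out, an alternative chosen after the data were examined, the intron odds ratio was 4.10 and that of 3′UTRs 4.01. UAUUUA most often started 4 nt upstream of the crosslinked base (1.17% of positions) or at that base (1.12%), against 0.122% at random. Tandem UUUA repeats, whose units are 4 nt long, were kept in here, and their part in these shares was not separated. The crosslinked base itself was U at 61.8% of positions.

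**Figure D3:**
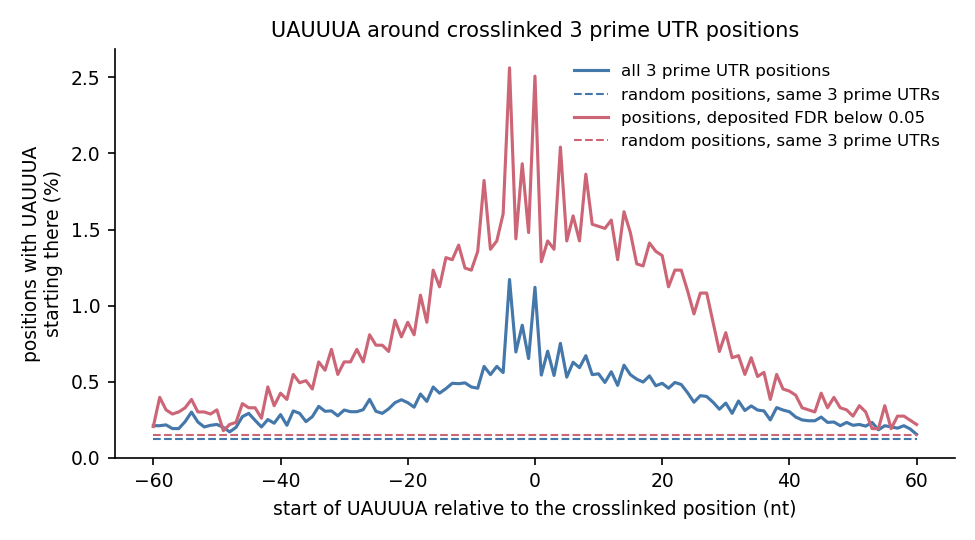
The share of 3′UTR positions with a UAUUUA starting at each distance from the crosslinked base (percent against nt) is drawn for all positions and for those at an FDR below 0.05, with dashed lines for random positions in the same 3′UTRs. The shares peak at -4 nt, with 1.17% of all positions and 2.56% of those at an FDR below 0.05. Tandem UUUA repeats were kept in.

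Other U-rich sequences were enriched as well. Of the 15 hexamers made of 4 U and 2 A, UAUUUA ranked 1 and its shifted neighbour AUUUAU ranked 2 (odds ratio 4.26), and the other 13 ranged from 2.07 to 2.99, the last being UAUUAU (2.78 to 3.22). At an FDR below 0.05 AUUUAU and UAUUUA had odds ratios of 10.4 each and the next hexamer 5.29. Among pentamers, the observed over random ratio was highest for UUUUU (3.48) and UUAUU (3.35), and AUUUA had 3.03.

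The last question was which groups of genes carried contacts in their 3′UTRs. Among the 12427 genes used as background 42.4% had a 3′UTR position, and 8 of the 18 gene lists tested had a higher share by Fisher's two-sided exact test. List members without any position in the table were not tested, so each share is one of the members found. A gene can enter this background through its 3′UTR position alone, and such a gene raises the share by its selection. With a background of genes with a coding or intron position, the same 8 lists passed. All 13 members found of the 15 genes for the ZFP36 family and other AU-rich element binding proteins had a 3′UTR position (100%, interval 75.3 to 100, adjusted exact p = 8.54e-05), and 9 of them had one at an FDR below 0.05. Of the G1/S cell cycle genes 21 of 24 had one (87.5%, 67.6 to 97.3, adjusted exact p = 7.25e-05), among them Ccnd2, a D-type cyclin, with 108 counts, Myc with 96, Rrm2, a ribonucleotide reductase subunit, with 50 and Cdk2 with 38. Cdk6, Mcm7 and Pcna had none by the authors' labels, with 3 counts in the M21 3′UTR of Pcna, 1 in that of Mcm7 and 57 intron counts in Cdk6. At an FDR below 0.05 the G1/S list no longer passed (5 of 24, adjusted exact p = 0.0615). Of the G2/M genes 16 of 22 had one (72.7%, 49.8 to 89.3, adjusted exact p = 0.0140), with Top2a at 71 counts, Cdk1 at 44, Birc5 at 34 and Kif11 at 12. Cdc25b and Cdc25c had none, and Ccnb1, the mitotic cyclin, had none by the authors' labels but 30 counts in its M21 3′UTR. Of the cell cycle inhibitor and quiescence genes 13 of 17 had one (76.5%, 50.1 to 93.2, adjusted exact p = 0.0147), with Cdkn1b, which encodes p27, at 41 counts, Trp53 at 27, Cdkn1a, which encodes p21, at 21 and Btg2 at 19, and none in Cdkn2a, Cdkn2c or Ccng2 by the authors' labels (26 counts in the M21 3′UTR of Ccng2).

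Immune, survival and histone gene lists also had higher shares. Of the AU-rich cytokine and immediate early genes 18 of 21 had a 3′UTR position (27 are listed, 85.7%, 63.7 to 97.0, adjusted exact p = 0.000291). Several of them, such as Il6, had no coding or intron count. Of those with a coding or intron position, 10 of 13 had one (76.9% against 40.1% of the other genes, adjusted exact p = 0.0176). Tnf had 279 counts, Il6 52, Junb 50 and Vegfa 36. There were none in Ifng, Egr1 or Dusp1, although 23 counts of Dusp1 labelled coding lie in its M21 3′UTR. Of the B cell identity and signalling genes 24 of 28 had one (85.7%, 67.3 to 96.0, adjusted exact p = 5.46e-05), with the transcription factor genes Ebf1 at 72 counts, Irf4 at 45, Ikzf1 at 36 and Irf8 at 34. Cr2 and Btk had none. Of the apoptosis regulators 14 of 18 had one (77.8%, 52.4 to 93.6, adjusted exact p = 0.0115), with Cflar, an inhibitor of caspase 8, at 93 counts, Pmaip1 at 41, Mcl1 at 28 and Bcl2 at 23, and none in Bcl2a1d, Bad or Xiap by the authors' labels (38 counts in the M21 3′UTR of Xiap). Of the histone genes 12 of 15 had one (80.0%, 51.9 to 95.7, adjusted exact p = 0.0147), with Hist1h2ab at 58 counts besides the leading genes and none in Hist1h2bc and Hist1h3b. The test takes each histone gene as independent, which near-identical copies may not be, so this p-value is uncertain.

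The remaining lists did not pass the test. Plasma cell genes had 7 of 9 (11 are listed, 77.8%, adjusted exact p = 0.0760), with the chaperone gene Hspa5 at 45 counts, Edem1 at 29, Mzb1 at 27 and Ell2 at 12, and none in Jchain or Il5ra, the interleukin 5 receptor. mRNA decay genes had 12 of 20 (adjusted exact p = 0.153), with Dcp2, the decapping enzyme, at 45 counts, the deadenylase genes Cnot6l at 34 and Cnot6 at 20, and none in Cnot1, Cnot3 or Cnot7 (24 counts in the M21 3′UTR of Cnot7). V(D)J recombination and class switch genes had 8 of 14 (16 are listed, 57.1%, adjusted exact p = 0.347), with Hmgb2 at 49 counts and Dclre1c at 8, and none in Dntt, Lig4 or Xrcc6. PI3K, mTOR and NF-kB genes had 15 of 23 (65.2%, adjusted exact p = 0.0674), with Nfkbia at 515 counts, Rel at 47 and Nfkb2 at 19, and none in Pdk1, Mtor or Tsc2 by the authors' labels (6 counts in the M21 3′UTR of Pdk1). Tnfaip3 of this list also had none by the authors' labels, but far more counts in its M21 3′UTR than Pdk1. With M21 regions 17 of 23 had one and the list passed (adjusted exact p = 0.0245), so its result depends on the labels. Notch genes had 6 of 8 (75.0%, adjusted exact p = 0.110), with Notch1 at 53 counts and Notch2 at 20, and none in Dll1 or Dtx1. Housekeeping genes had 13 of 21 (61.9%, adjusted exact p = 0.110), with Tubb5 at 109 counts and Hsp90ab1 at 32, and none in Gapdh, Tuba1b or Ppia. Ribosomal protein genes had 6 of 26 (23.1%, 8.97 to 43.6, adjusted exact p = 0.0792), with Rpl4 at 2 counts and Rpl19, Rpl23 and Rpl5 at 1 each, and none in Rplp0, Rpl3 or Rpl7. Other members had none by the authors' labels but counts in their M21 3′UTR, such as Rps3 with 9 and Rpl13a with 6. Their low share thus rests in part on the authors' labels.

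Against random lists of like 3′UTR length, all 8 lists passed again (permutation within length classes). The housekeeping genes, which had not passed the first test, passed this one (61.9% against 30.1%, permutation adjusted p = 0.00874). With matching on coding counts as well, an alternative chosen after the data were examined, the G1/S, AU-rich cytokine and B cell lists passed (permutation adjusted p = 0.0024 each) and the other lists did not, with adjusted p from 0.0612 to 0.122 for the 5 that had passed the first test. Both matched tests kept genes that entered the background through a 3′UTR position alone.

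**Figure D4:**
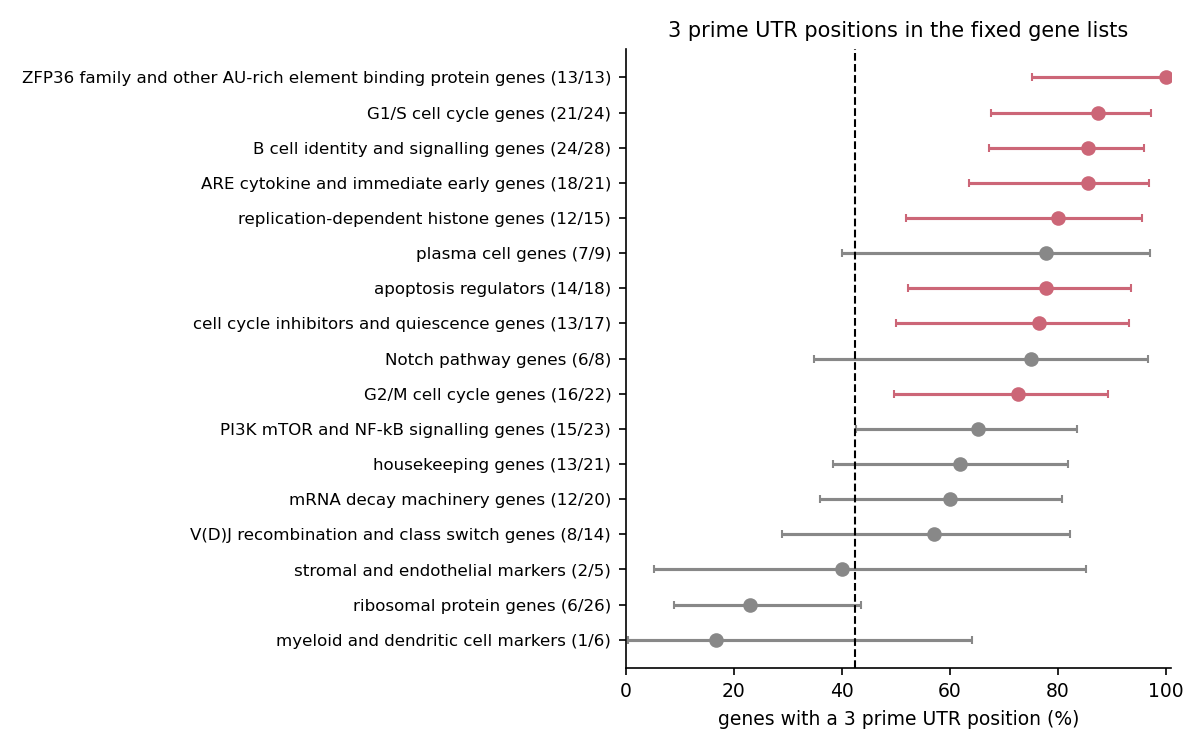
The share of genes with a 3′UTR position (percent, exact binomial 95% intervals) is plotted for each fixed gene list with at least 5 genes in the background, with the number of genes in brackets and the share of all background genes, 42.4%, as a dashed line. The 8 lists in red had an adjusted Fisher p below 0.05, among them the ZFP36 family list at 100% and the G1/S list at 87.5%.

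Among genes with a 3′UTR position, some lists also had more counts per gene. RNA levels were not analysed here, so more mRNA cannot be told apart from more contacts per mRNA in these differences. The mean log2 count exceeded that of the other genes by 3.17 for the ZFP36 family list (13 genes, permutation adjusted p = 5e-05), by 2.66 for histones (12 genes, 5e-05), by 2.33 for housekeeping genes (13 genes, 5e-05) and by 1.82 for AU-rich cytokine and immediate early genes (18 genes, permutation adjusted p = 0.000112). The 12 histone genes may not be independent, since near-identical copies make the assignment of their counts uncertain. Smaller excesses were found for plasma cell genes (1.47, adjusted p = 0.0266 by permutation), cell cycle inhibitors (1.38, 0.00687), PI3K, mTOR and NF-kB genes (1.35, 0.00447), apoptosis regulators (1.16, 0.0160), G1/S genes (1.02, 0.0103) and B cell genes (0.74, 0.0357). G2/M genes (0.67, permutation adjusted p = 0.130), Notch genes (0.93, 0.185), mRNA decay genes (0.65, 0.185) and V(D)J genes (-0.08, 0.894) did not pass. Ribosomal protein genes were lower by log2 -1.69 (6 genes, permutation adjusted p = 0.0194), but per kb of 3′UTR they lay 1.11 above the other genes (adjusted p = 0.190). Per kb, 7 lists passed: 6 of those above and the G2/M list, which had not passed before (2.07), while the plasma cell, NF-kB, apoptosis and B cell lists no longer did.

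Outside 3′UTRs, the leading genes were of other kinds. Ebf1, a transcription factor that specifies B cells, had 2374 intron counts, Phip 1442, Zbtb20 1064, Cd74, the invariant chain of MHC class II, 1022 and Foxp1 1010. In Zbtb20 a single 15 nt sum reached 620, and tandem UUUA repeats held 46.8% of the intron counts of Cd74 and 29.8% of those of Phip, against 7.29% for Ebf1 and 8.61% for Foxp1. In coding sequence the mitochondrial mRNAs led, with mt-Nd1 at 1088 counts, mt-Co1 at 342, mt-Cytb at 194, mt-Nd5 at 186 and mt-Nd6 at 154. Among non-coding RNAs the mitochondrial ribosomal RNAs mt-Rnr2 and mt-Rnr1 had 8625 and 2682 counts, and the predicted genes Gm26924, Gm24871 and Gm24049 had 3107, 1583 and 810. By class, small nuclear RNAs held 6554 counts (1.15% of the total), small nucleolar RNAs 4485 and long intergenic RNAs 4395. In the non-coding list Rn7sk, the RNA that restrains transcription elongation, had 324 counts and Neat1 had 12, while Malat1 had 134 counts labelled non-coding and 633 labelled intron.

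Marker genes of other cell types had few counts. The B cell list held 6059 counts over all regions. The T cell markers held 9 counts in 2 of 13 genes, of which 8 were in introns of Lck, and the myeloid and dendritic markers 13 counts in 6 of 12 genes. The erythroid markers had 1 count, in an intron of Slc4a1. The stromal and endothelial markers held 158 counts, and 136 of these lay in introns of Pecam1, which encodes the adhesion molecule CD31. The share of genes with a 3′UTR position did not pass the test for the T cell, myeloid or stromal markers (2, 6 and 5 genes tested, Fisher's exact test, adjusted p = 1, 0.463 and 1).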

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

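1 result is listed here, a count and not a test. Stretches that the authors' table places at chromosome ends held 1076 counts at 535 positions, above the 3 counts that a count of 0 allows. They enter the totals of the region shares, and no comparison uses them otherwise. Their highest 15 nt sum was 242, and 26.9% of these counts lay in or within 15 nt of runs of at least 12 U.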

How the results depend on the processing

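These settings were chosen after the data were examined: an FDR below 0.05, M21 regions with the 3′UTR first, densities with M21 labels, nuclear genes alone, mean sums, positions with a 15 nt sum of 1, rotated positions, repeats left out, list members matched by the table's symbol alone, and matching on coding counts. Of 272 alternative values, 195 kept their direction and their side of the threshold (or stayed within the interval or 1.5 times the count), 40 moved, 18 lost the threshold, 16 gained it and 3 reversed. The cause was not tested for those that changed. The motif odds ratio stayed above 1 in all 15 alternatives, from 2.24 to 10.8, among them 3 other AU-rich motifs and the coding and intron positions. Alternatives that leave out a replicate, require at least 2, 3 or 4 libraries, or count positions within 15 nt as shared between libraries could not be run, because the libraries are pooled, and a whole peak within the 3′UTR is the same as an overlap for positions of 1 nt. With a background of genes with a coding or intron position the T cell markers gave no value. No analysis paired by library was possible because there is 1 group and its libraries are pooled in 1 column. Regions were not paired by gene in the height tests. Depth limits statements on single genes, since 29.0% of the genes with a 3′UTR position have exactly 1 count.

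By region, weighting by counts gave 7.45% for 3′UTRs, 4.27% for coding sequence, 58.4% for introns, 5.53% for non-coding RNAs and 23.9% for intergenic sequence. In that order, an FDR below 0.01 gave 6.94%, 2.67%, 55.8%, 3.31% and 30.9%, an FDR below 0.05 gave 6.96%, 2.64%, 57.3%, 3.19% and 29.6%, a 15 nt sum of at least 2 gave 11.2%, 4.10%, 59.5%, 4.51% and 20.3%, and neighbours merged within 15 nt gave 6.97%, 5.07%, 67.0%, 0.759% and 19.8%. M21 regions gave 9.14% for 3′UTRs, 2.63% for coding sequence, 62.7% for introns and 2.24% for non-coding RNAs, and with coding sequence first 9.09%, 2.67%, 62.7% and 2.24%, where the density in 3′UTRs was 5.49 times that in introns and 4.47 times that in coding sequence, against 4.79 and 2.09. The number of genes with a 3′UTR position was 895 at an FDR below 0.01, 949 at 0.05 and 2371 with a 15 nt sum of at least 2, against 5351, and 3783 with at least 2 positions, 5736 with 3′UTRs extended by 1000 nt and 5919 with M21.

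The difference in median peak height was 0 against introns and coding sequence, with gene medians, which were 1 in each region at the median, and with 15 nt sums of at least 2, a selection on the compared value itself, so neither shows that the difference is absent. The mean difference with gene medians was 0.114 from introns (permutation p = 0.477) and 0.607 from coding sequence (p = 1e-05), and with sums of at least 2 it reversed to -0.163 from introns and -0.476 from coding sequence.

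For gene lists, adjusted p became 0.00874 for housekeeping genes with random lists of like 3′UTR length. With coding counts matched too, 3 lists passed, and G2/M had 0.0732, ZFP36 family 0.0843, apoptosis 0.0612, inhibitors 0.122 and histones 0.0612. An FDR below 0.01 gave G1/S 0.142 and housekeeping 5.38e-05, and an FDR below 0.05 gave 0.0615 and 5.83e-05. NF-kB genes had 0.0310 against genes with a coding or intron position, 0.00333 with sums of at least 2, 0.0153 with at least 2 positions and 0.0245 with M21. Plasma cell genes passed in 4 settings, with 0.0248 when matched by the table's symbol alone, which leaves out Jchain, 0.0176 against genes with a coding or intron position, 0.0247 with sums of at least 2 and 0.00778 with at least 2 positions. Housekeeping genes had 0.00144 with sums of at least 2 and 0.00600 with at least 2 positions, where ribosomal protein genes had 0.00443 with a lower share (3.85% against 30.1%), while against random lists of like length their share was 23.1% against 22.0%. With M21 regions the ribosomal protein genes did not pass. Over its 9 alternatives adjusted p ranged from 1.22e-05 to 0.142 for G1/S, from 1.87e-07 to 0.0176 for AU-rich cytokines and from 3.05e-07 to 0.0278 for B cell genes.

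For strength, the log2 differences by highest 15 nt sum were 0.29 for B cell genes (no longer past the threshold), 0.77 for G2/M (now past it) and -0.65 for ribosomal protein genes (no longer). Per kb, 7 lists passed against 11, with G2/M at 2.07 (now past it), and B cell 0.83, NF-kB 0.91, apoptosis 1.10 and plasma cell 1.35 no longer. Ribosomal protein genes reversed to 1.11.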

Other observations

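The tests of U preference and mRNA abundance and the grouping by repeats were chosen after the results were seen, the test of 3′UTR length was planned but its prediction was written after its result, and leaving out tandem UUUA repeats was added after the data were examined but before its result was seen. Most intron positions (84.9%) lay outside tandem UUUA repeats and runs of U or A, but these repeats and U runs held far more positions than their share of bases. Tandem UUUA repeats of at least 3 units, counted with 15 nt on each side, held 8.79% of intron positions (exact binomial 95% interval 8.69 to 8.89), while they make up 0.121% of intron bases in the genes concerned. At an FDR below 0.05 their share of intron positions was 32.4% (32.0 to 32.7), and 48.9% lay outside repeats and runs. In 3′UTRs the same repeats held 1.62% of positions (1.49 to 1.75) on 0.0632% of bases. Runs of at least 12 U held 5.54% of intron positions on 0.396% of bases and 4.50% of 3′UTR positions on 0.481% of bases. Intergenic positions lay in tandem UUUA repeats at 14.8%, in U runs at 14.9% and in A runs of the same length at 7.41%.

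Among the genes with the most intron counts the repeats took very different shares. In Cd74, which encodes the invariant chain of MHC class II, 46.8% of 1022 intron counts lay in tandem UUUA repeats, with a 15 nt sum of 355 at chromosome 18 position 60804167. In Ikzf1, a transcription factor gene of lymphocytes chosen after its values were seen, it was 42.1% of 748 counts, with a sum of 224 at chromosome 11 position 11717128, and in Phip 29.8% of 1442 counts. Ebf1 and Foxp1 had 7.29% of 2374 and 8.61% of 1010 counts in such repeats, so that most of their intron counts lay elsewhere. In Zbtb20 a single point at chromosome 16 position 43168221 reached a sum of 620, in neither kind of repeat. Of the 100 highest pile-ups in introns and intergenic sequence, at least 100 nt apart, 16 lay in tandem UUUA repeats, 23 in U runs, 19 in A runs and 42 in none of these.

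Technical explanations were weighed for the motif enrichment in 3′UTRs, for that in introns, with its excess over 3′UTRs, and for the gene lists, and no biological explanation was tested, because the design has 1 group. UAUUUA was enriched around 3′UTR positions (odds ratio 4.34). A preference of ultraviolet crosslinking for U-rich sequence that rested on base composition alone would enrich all hexamers of like composition to the same degree. The odds ratio of UAUUUA was 1.45 times that of the highest of the other 13 hexamers of 4 U and 2 A (bootstrap 95% interval 1.32 to 1.59), leaving aside its shifted neighbour AUUUAU, which argues against a preference for composition alone as the whole cause. The other 13 themselves ranged from 2.07 to 2.99. A crosslinking preference that depends on the order of the bases was therefore not tested. Tandem UUUA repeats were kept in this ratio. Without tandem UUUA repeats and 31 nt around them the odds ratio was 4.01 (3.82 to 4.23), so these repeats do not account for it either. A part of the enrichment may still come from U preference, since UUUUU was the most enriched pentamer and all 15 hexamers had odds ratios above 2.

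UAUUUA was more enriched around intron positions (odds ratio 7.48) than around 3′UTR positions (4.34). With tandem UUUA repeats left out, the intron odds ratio was 4.10 (bootstrap 95% interval 4.03 to 4.18), above 1, which argues against the repeats as the whole source of the intron enrichment. Beside the 3′UTR value of 4.01 (3.82 to 4.23), however, the intervals overlap, so whether introns exceed 3′UTRs outside these repeats cannot be told apart from no difference. Tandem UUUA repeats themselves contain UAUUUA, so leaving them out also removes sites that the protein may bind. The fall from 7.48 to 4.10 thus does not separate a technical source from binding. Whether reads from such repeats were placed at 1 site or several by the authors' alignment is not given in the sources used here and stays open.

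If 3′UTR length caused the higher share of genes with a 3′UTR position in 8 gene lists, random lists of like length would have the same share. All 8 lists passed against these random lists, which argues against length alone as the cause. Abundance was weighed with coding counts as a stand-in, which is itself a count of contacts and not of mRNA. With both matched, 3 lists still passed, and the calls of 5 ended as the shares of the random lists rose: the ZFP36 family list stood at 100% against 74.3%, G2/M at 72.7% against 48.9%, inhibitors at 76.5% against 52.0%, apoptosis at 77.8% against 50.9% and histones at 80.0% against 48.0%. For none of the 8 lists can abundance be told apart from a preference for their mRNAs, because RNA levels were not analysed here. Of 12763 protein-coding genes with any position, 5340 had a coding sequence position, so coding counts do not rank the others. The 3 lists that passed exceeded random lists of like length and coding counts, which does not exclude abundance for them. Both matched tests kept genes that entered the background through a 3′UTR position alone, and they were not rerun without such genes. The AU-rich cytokine list had 18 of 21 in this background and 10 of 13 among genes with a coding or intron position. Its matched values thus rest in part on that selection.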
